A study of Mus musculus with 6 samples.

How the data were processed

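Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on cardiac neural crest cells of mouse embryos at embryonic day 10.5. Per the labels, the cells carried green fluorescent protein from the mTmG reporter after recombination by Wnt1-Cre2, a driver of the neural crest lineage, and were isolated by fluorescence-activated sorting from pharyngeal arches 3 to 6. Chromatin was precipitated with antibodies against CHD7, a chromatin remodelling ATPase, or against H3K27ac, acetylated lysine 27 of histone H3, and input chromatin was sequenced beside it. Each of these 3 groups had 2 libraries, numbered 1 and 2 in the labels. The labels do not say that the samples of a group came from separate litters or sorts, so p-values between libraries measure only the spread between these samples, which may be technical.

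The submitters' processing notes name bcl2fastq 2.18.0.12, Bowtie2 2.3.3.1, Picard, MACS2 2.1.2 and the mouse genome build mm10. The deposited files are peak lists, each called on a single library by the authors and not on pooled samples. Each peak carries the fold enrichment at its summit, a ratio computed by the authors' peak caller. The deposited lists also give the p-value and the q-value of each peak as −log10, and an integer score derived from the q-value. Whether the input libraries served as the control of the peak calls is not given in the sources used here. The lists hold no read counts, so the depth of each library is unknown and no counting interval was computed from reads. A deeper library yields more called peaks, so numbers of peaks were not compared between groups as levels. Fold and q-value are the authors' values per peak and were used to describe, rank or filter peaks within a list and to compare peaks of the same list, with and without H3K27ac by fold and on the X chromosome and the autosomes by −log10 q at the same fold. Between the libraries of a group, the fold of the same regions was correlated by rank and given as a mean with SD. The scale of fold in each library is that of the authors' peak caller, so fold was not tested between antibodies.

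Rows of the lists that gave several summits of the same interval were joined into 1 peak with the highest fold and q-value, and peaks on chromosomes 1 to 19, X and Y were kept. This left out between 27 and 75 peaks of each ChIP library and 101 and 106 peaks of the input libraries. A consensus region of a group was the merged extent of overlapping peaks of its libraries, kept where both libraries had a peak in it. Overlap meant at least 1 bp. Genes were taken from a RefSeq gene table of the same build, which gives the start and end of each gene without its strand or its exons. A transcription start site could not be told from a gene end, so the promoter class planned before the data were examined was replaced by a boundary class, which holds regions within 1 kb of either annotated end of a protein-coding gene. The remaining regions, called distal, were divided into gene body and intergenic, and no exon or intron was assigned. Of 21900 protein-coding genes, 124 were left out because they carried coordinates of unplaced sequence, starting below position 3000000, or below 500000 on the Y chromosome, and 21776 were used. The joining of summits, the choice of chromosomes and this filter were settled after the files had been seen.

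Chance overlap was measured by 1000 rotations of the regions along each chromosome, in a one-sided permutation test whose smallest p is 0.001, and for the overlap of CHD7 with H3K27ac also by 1000 random placements within 4 classes of distance from a gene boundary, limited at 1, 10 and 100 kb. Genes and regions with and without a feature were compared by Fisher's exact test, two-sided, and odds ratios carry a 95% confidence interval from the log odds ratio. Genes and regions are not independent replicates, so these tests describe these lists. Fold enrichment of CHD7 peaks with and without H3K27ac was compared within each library by a two-sided permutation test with 100000 resamples. The share of peaks at boundaries was compared between the antibodies by the exact permutation test of 2 against 2 libraries, which cannot give a p below 0.333.

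Before the data were examined, 21 gene lists were fixed, with 441 different genes, all found in the gene table. They cover neural crest specifiers, cardiac neural crest and outflow tract genes, pharyngeal arch patterning genes, anterior and posterior Hox genes, semaphorin and axon guidance genes, and genes of BMP and TGF-beta, WNT, NOTCH, and retinoic acid and hedgehog signalling. They also cover smooth muscle and matrix genes, chromatin regulators, housekeeping genes, adult tissue genes, and markers of neurons and ganglia, glia and melanocyte precursors, cardiomyocytes, endothelium, blood cells, epithelium and endoderm, and mesoderm and skeletal muscle. In all, 16 genes stood in more than 1 list. Regions at boundaries were tested per list by Fisher's exact test against all other protein-coding genes. Distal regions were assigned to the gene with the nearest boundary within 100 kb, and their number per member was compared with 10000 random lists matched on the length of genome nearest to each gene in 10 classes (one-sided permutation test, smallest p 1e-04). Adjusted p-values are Benjamini-Hochberg values over the 21 lists, with a threshold of 0.05.

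The named genes followed a rule fixed before the data were examined. They were Chd7 itself; the nearest genes of the 10 boundary and 10 distal CHD7 regions and of the 10 distal H3K27ac regions with the highest mean percentile of fold over both libraries, without regions that overlapped an input peak; the 10 genes with the most distal CHD7 regions; up to 4 members of each list with the highest CHD7 percentile at the boundary and up to 2 members, in list order, without CHD7 there; and the 10 longest stretches of H3K27ac regions joined over gaps of up to 10 kb. Some genes that the rule names are not reported here. Coordinates are those of mm10, counted from 1.

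Alternatives fixed before the data were examined were peaks with a −log10 q of at least 10, the 10000 peaks of lowest q per library, exclusion of peaks that overlap an input peak, overlap of at least 50% of a region, regions with a peak in either library, each library left out, boundary windows of 500 bp and 2.5 kb, a limit of 50 kb for distal regions, and same-numbered libraries compared as a block. Alternatives used 10000 resamples of peaks. The planned counts of 21 sequence motifs at peak summits were not run because a genome sequence was not used here. The overlap, rotation, placement, gene list and fold procedures were tested on simulated data, and the permutation of 2 against 2 libraries and the draws of matched genes and regions were not. The overlap routine gave the brute-force answer for 2000 of 2000 regions, and 1 of 40 unrelated region sets had p below 0.05 by rotation. By placement, p lay below 0.05 for 1 of 20 unrelated sets spread evenly within the distance classes and for 5 of 20 centred on gene boundaries, which overlapped in 6.91% of cases against 6.28% for their placements, so placement understated chance for such sets. Over 21776 genes, 19 of 20 lists of 25 genes with 85% occupancy against a background of 44% were called, as were 19 of 20 lists with 3 times the distal rate, and 0 of 200 unrelated lists in either test. On 31873 peaks, a planted log2 fold difference of 0.20 was recovered as 0.202. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.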

Results

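CHD7, a chromatin remodelling ATPase, and H3K27ac, a histone acetylation found at active promoters and enhancers, were mapped by ChIP-seq in sorted cardiac neural crest cells, the part of the neural crest that passes through the caudal pharyngeal arches towards the outflow tract of the heart. The CHD7 libraries held 31873 and 26927 peaks on the placed chromosomes, with median widths of 463 and 470 bp, and the H3K27ac libraries held 24283 and 22686 peaks of 543 and 549 bp. The median fold enrichment given by the authors' peak caller was 3.19 and 3.24 for CHD7 and 3.59 and 3.68 for H3K27ac. Peaks called in the input libraries were few, 451 and 512, and narrow, 109 and 110 bp, with a median fold of 7.55 and 7.10. The depth of the libraries is unknown.

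The CHD7 and H3K27ac maps each recurred between their libraries far above chance. Of the peaks of CHD7 library 2, 76.6% overlapped a peak of library 1, against 1.39% for rotated lists, and 65.1% of the peaks of library 1 overlapped library 2. For H3K27ac, 81.3% of the peaks of library 2 and 75.8% of those of library 1 overlapped the other library, against 1.23% by chance for the first of these. The overlap of library 2 with library 1 exceeded all 1000 rotations for both antibodies (permutation p = 0.001, the smallest they can give, one-sided). Across the 19947 CHD7 consensus regions, fold enrichment of the libraries correlated with a Spearman rho of 0.62, and across the 17756 H3K27ac regions with 0.81. These are correlations across regions, which are not independent replicates. CHD7 peaks found in 1 library alone had a lower median fold, 2.87 against 3.44 for the shared peaks of library 1, and 2.93 against 3.38 in library 2. Peaks of the input libraries overlapped 0.995% and 1.21% of the CHD7 peaks and 0.828% and 0.802% of the H3K27ac peaks, a mean of 0.959% against 0.0147% for rotated lists (permutation p = 0.001). In the other direction, between 70.5% and 77.2% of the input peaks overlapped a CHD7 peak and between 42.2% and 47.7% an H3K27ac peak, over the pairs of libraries.

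The first comparison asked where CHD7 lies in the genome of these cells. Of the 19947 CHD7 consensus regions, 10197 (51.1%) lay within 1 kb of a boundary of a protein-coding gene, 4813 (24.1%) lay in gene bodies and 4937 (24.8%) between genes. Of the 17756 H3K27ac regions, 11214 (63.2%) lay at boundaries, 3531 (19.9%) in gene bodies and 3011 (17.0%) between genes. Rotated regions lay at boundaries in 4.28% of cases for CHD7 and 4.46% for H3K27ac (permutation p = 0.001 each, the smallest possible, one-sided). Per library, 44.6% ± 2.99 (SD, n = 2) of CHD7 peaks and 54.7% ± 1.13 (SD, n = 2) of H3K27ac peaks lay at boundaries, against 3.77% and 5.66% of the input peaks. The difference of 10.1 percentage points exceeded the spread within both groups, but its exact permutation p of 0.333 is the smallest that 2 against 2 libraries allow. Longer lists had a lower share, with 42.5% of 31873 and 46.7% of 26927 CHD7 peaks. For H3K27ac it was 53.9% of 24283 and 55.5% of 22686 peaks. Peaks found in 1 library alone lay at boundaries in 26.8% and 34.6% of cases for CHD7 and 26.1% and 23.7% for H3K27ac. The antibody and the length of the list were thus not told apart. Among 13917 genes longer than 10 kb, CHD7 lay at 1 end of 6691 and at both ends of 517, and H3K27ac at 1 end of 7475 and at both ends of 276.

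The strongest boundary CHD7 region that avoided input peaks overlapped a boundary of H2bc1, a histone H2B gene, on chromosome 13 at 23933596 to 23934128, with folds of 11.3 and 10.7 in libraries 1 and 2 and no H3K27ac region. It was followed by regions at H4f16, a histone H4 gene (6, 136803478 to 136805005, folds 9.12 and 9.25), Vat1l (8, 114205189 to 114205810, folds 8.18 and 10.4), Zfp280d (9, 72274358 to 72274960, folds 10.3 and 8.26) and Klhl24 (16, 20097486 to 20098165, folds 9.75 and 7.84). Rbmxl1, Zfp869, Plekhg1, Hectd3 and Dyrk1b completed the 10, with mean folds between 7.84 for Dyrk1b and 8.46 for Rbmxl1. H3K27ac overlapped all of these regions but those of H2bc1, Vat1l and Hectd3. Chd7 itself, the gene of the mapped protein, had no CHD7 peak at either boundary in either CHD7 library. An H3K27ac region with folds of 4.15 and 4.39 lay 166 bp inside its lower boundary (4, 8690568 to 8691124). Of the 4 distal CHD7 regions nearest to Chd7, those at 8666880 to 8667432 and 8799371 to 8800119 lacked H3K27ac, with mean folds of 3.60 ± 0.20 and 2.498 ± 0.06 (SD, n = 2). The other 2, at 8850541 to 8851178 in the gene body and 8910706 to 8911894 beyond it, overlapped H3K27ac, with mean folds of 2.70 ± 0.48 and 3.01 ± 0.76.

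**Figure D1:**
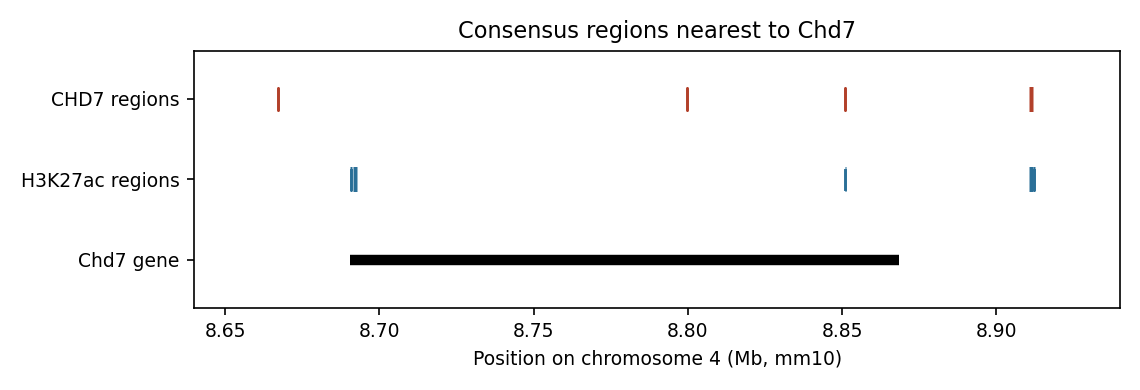
Consensus regions of CHD7 and H3K27ac nearest to Chd7 along chromosome 4 (horizontal axis in Mb of mm10), with the annotated extent of the gene as a black bar and each region as a vertical mark at its position. The 4 CHD7 regions are distal, and H3K27ac but not CHD7 lies at the lower boundary of the gene.

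The second comparison asked how far CHD7 and H3K27ac coincide. H3K27ac overlapped 12051 of the 19947 CHD7 regions (60.4%), and CHD7 overlapped 11854 of the 17756 H3K27ac regions (66.8%). Rotated regions overlapped in 1.12% and 1.28% of cases, and regions placed at random within classes of distance from gene boundaries in 8.62% and 9.84% (permutation p = 0.001 for each, the smallest possible, one-sided). Boundary CHD7 regions carried H3K27ac in 80.4% of cases and distal CHD7 regions in 39.5%, an odds ratio of 6.27 (95% interval 5.88 to 6.68; Fisher's exact test, p too small for the computation to represent). Of the distal CHD7 regions, 2133 of 4813 in gene bodies and 1721 of 4937 between genes overlapped H3K27ac, leaving 5896 distal CHD7 regions without it. In the other direction, 72.0% of boundary and 57.7% of distal H3K27ac regions overlapped CHD7. With peaks limited to a −log10 q of at least 10, the share of H3K27ac regions that overlapped CHD7 was 27.8%, against 61.8% for CHD7 regions that overlapped H3K27ac. The median −log10 q was 4.99 and 5.31 in the CHD7 libraries and 7.14 and 7.40 in the H3K27ac libraries. The same limit can thus remove a larger part of the CHD7 lists, so the lower share does not show that strong H3K27ac sites lack CHD7.

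CHD7 peaks that overlapped H3K27ac had the higher fold enrichment. The median fold was 3.45 with and 3.00 without H3K27ac in library 1, a log2 difference of 0.20, and 3.48 and 3.06 in library 2, a log2 difference of 0.19 (permutation test over peaks, two-sided, p = 1e-05 in each library, the smallest possible). In the highest decile of CHD7 fold, H3K27ac covered 94.8% of boundary and 51.7% of distal CHD7 regions, and in the lowest decile 52.4% and 32.9%. The log2 difference was −0.00518 (mean of both libraries, larger permutation p of 0.40) among peaks with a −log10 q of at least 10, and 0.0508 (larger permutation p of 1e-04, the smallest possible) among the 10000 peaks of lowest q. Both limits also applied to the H3K27ac lists, so CHD7 peaks over weaker H3K27ac peaks counted as without H3K27ac. They also narrowed the range of CHD7 peaks compared. These values thus do not show that the difference is absent among strong CHD7 peaks.

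**Figure D2:**
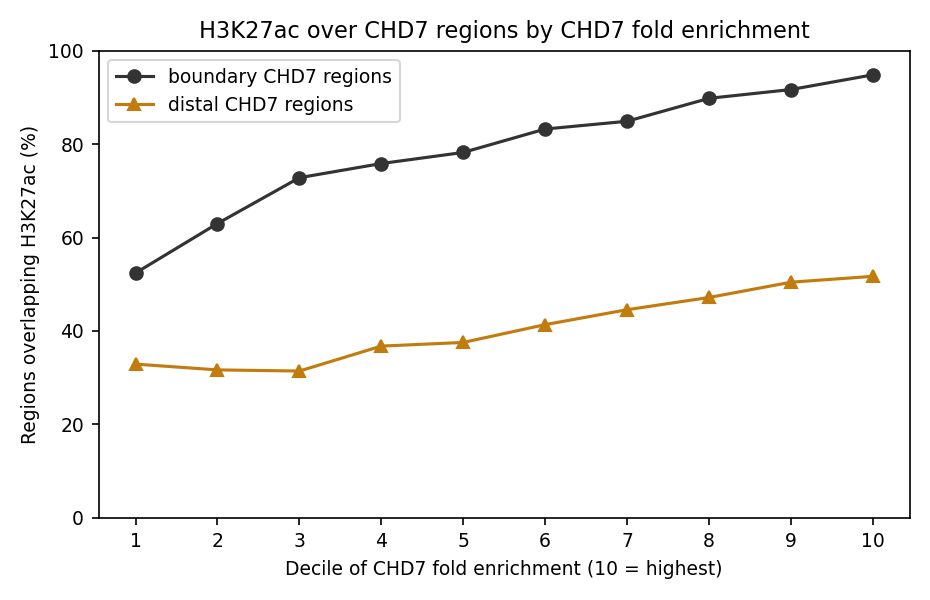
Share of CHD7 consensus regions that overlap H3K27ac (percent) by decile of CHD7 fold enrichment, for boundary regions (circles) and distal regions (triangles). The boundary share runs from 52.4% in the lowest to 94.8% in the highest decile, and the distal share from 32.9% to 51.7%.

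Over genes, both were mostly found at boundaries of the same genes. Of 21776 protein-coding genes, 8567 had CHD7 and H3K27ac at a boundary, 1051 had CHD7 alone, 1805 had H3K27ac alone and 10353 had neither. Both could lie at different ends of a gene, and an overlap was not required. H3K27ac lay at 89.1% of the genes with CHD7 and at 14.8% of the others, an odds ratio of 46.8 (95% interval 43.1 to 50.7; Fisher's exact test, p too small for the computation to represent). The odds ratio was 14.8 with a −log10 q of at least 10 and 81.9 with regions found in either library.

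Of the 10 strongest distal CHD7 regions, 8 lacked H3K27ac, while each of the 10 strongest distal H3K27ac regions overlapped CHD7. Over more regions, 16 of the 50 strongest distal CHD7 regions overlapped H3K27ac, as did 24 of the next 50, 51 of the 100 after these and 115 of the following 200. The CHD7 regions nearest to Acvr1b, an activin receptor gene (15, 101196073 to 101196825, folds 12.5 and 11.97), Gmfg-ps (6, 4923698 to 4924368, folds 12.1 and 11.1), D7Ertd443e (7, 134423746 to 134424365, folds 10.7 and 12.3), Helb (10, 119953058 to 119953633, folds 11.1 and 10.7), Sorcs2, Kif6, Diaph2 and Bicc1 lacked it, and those nearest to Kif2c and Nxnl2 did not. The Acvr1b region lay in a gene body, 16.9 kb from the nearest boundary. Those named for Diaph2, Helb and Kif6 lay 693, 130 and 102 kb from the nearest boundary. This is beyond the 100 kb within which distal regions were assigned to genes of the lists. The distal H3K27ac regions lay nearest to Nfyc, a subunit of the CCAAT-binding factor NF-Y (4, 120824792 to 120825812, folds 11.7 and 12.7), Smim10l1 (6, 133104837 to 133105963, folds 12.5 and 11.7), Ptpdc1, Kif2c, Snx6, Tex14, Pfdn4, Eapp, Pom121l2 and Rbm12b1.

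The next comparison asked which groups of genes carried CHD7 at a boundary. Chromatin regulators (23 of 28 members, 82.1%) and housekeeping genes (23 of 27, 85.2%) had CHD7 more often than other protein-coding genes, of which 44.1% had it. Posterior Hox genes (1 of 16), which pattern the trunk and limbs, cardiomyocyte markers (0 of 14) and adult tissue genes (3 of 30) had it less often. Adjusted p-values (Fisher's exact test) were 0.000492, 0.000347, 0.00697, 0.00255 and 0.000492 in that order. The posterior Hox genes lie close together in clusters, so these members are not independent. Among all genes with H3K27ac at a boundary, 82.6% had CHD7. Of the members with H3K27ac there, 22 of 25 chromatin regulators and 22 of 25 housekeeping genes had it. The higher calls of both lists thus set no preference of CHD7 beyond that for boundaries with H3K27ac. H3K27ac lay at 0 of 16 posterior Hox genes, 0 of 14 cardiomyocyte markers and 4 of 30 adult tissue genes. CHD7 lay at 2 of these 4 adult tissue genes. The lower calls thus set no avoidance by CHD7 beyond the lack of H3K27ac. The histone deacetylase genes Hdac2 (folds 6.66 and 5.72) and Hdac1 (5.29 and 4.25) and the histone methyltransferase genes Kmt2b (6.24 and 5.19) and Kmt2a (4.23 and 5.77) led the chromatin regulators, while Chd7 and Kdm6a, the latter on the X chromosome, where CHD7 peaks were called at fewer genes, had H3K27ac without CHD7. Vps29 (5.65 and 4.99), Vcp (4.50 and 4.82) and Snrpd3 led the housekeeping genes, and Tbp and Psmb4 had H3K27ac alone. Hoxa10 was the posterior Hox gene with CHD7 (2.51 and 2.41), and Hoxa9 and Hoxa11 had none. Nkx2-5 and Myh6 were among the cardiomyocyte genes without CHD7, and Krt10, Sftpc and Acta1 were the adult tissue genes with it. The calls of posterior Hox, cardiomyocyte and adult tissue genes were lost with a −log10 q of at least 10 (log2 odds ratios −1.97, −1.78 and −1.22, against −3.03, −4.52 and −2.64 with all peaks) and with the 10000 peaks of lowest q (−3.06, −2.87 and −1.53, adjusted p 0.18 for each). BMP and TGF-beta signalling was called higher without CHD7 replicate 2 (log2 odds ratio 1.58).

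No list of neural crest, arch or signalling genes passed the test for CHD7 at boundaries. CHD7 lay at 9 of 24 neural crest specifiers, 16 of 32 cardiac neural crest and outflow tract genes, 6 of 25 pharyngeal arch patterning genes, 3 of 15 anterior Hox genes and 18 of 34 semaphorin and axon guidance genes (adjusted p 0.67, 0.69, 0.14, 0.18 and 0.40). The neural crest transcription factor genes Ets1 (folds 3.75 and 3.75), Sox8 (3.79 and 3.12), Snai2 (3.49 and 2.94) and Mycn (3.35 and 3.05) had CHD7, and Sox10 and Tfap2a did not. Bmpr1a (4.79 and 4.17) and Tgfbr2 (4.36 and 3.82), receptors of BMP and TGF-beta, and Nf1 and Fn1 led the cardiac neural crest genes, and Hand1 and Hand2 had no CHD7. Eya1 (3.41 and 2.91), Tshz2 and Osr2 had CHD7 among arch genes, and Dlx1 and Dlx2 did not. Hoxd1 (3.44 and 3.35), Hoxa5 (2.44 and 2.52) and Hoxa2 (2.00 and 2.07) were the anterior Hox genes with CHD7, and Hoxa3 was among those with none. Plxna1 (6.07 and 4.02), a semaphorin receptor, Sema4b (3.87 and 3.29), Robo1 and Plxnd1 led the axon guidance genes, and Sema3a and Sema3b had no CHD7 there. CHD7 and H3K27ac both lay at a boundary, not necessarily the same end, of 6 neural crest specifiers, 12 cardiac neural crest genes, 2 anterior and 0 posterior Hox genes and 13 semaphorin and axon guidance genes.

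Signalling genes and markers of other cell types ranged on either side of the 44.1% of other genes without passing the test within 1 kb, apart from the cardiomyocyte markers given above. CHD7 lay at 18 of 30 BMP and TGF-beta genes, 13 of 31 WNT genes, 9 of 20 NOTCH genes, 13 of 23 retinoic acid and hedgehog genes and 12 of 20 smooth muscle and matrix genes (adjusted p 0.23, 0.95, 1, 0.40 and 0.29). Lrp6 (3.72 and 4.10) and Ctnnb1 (3.71 and 3.83), a WNT receptor and beta-catenin, Notch2 (3.82 and 4.10), Smo (3.39 and 4.72), the transducer of hedgehog signalling, and Itga8 (4.97 and 4.40) carried it. It lay at 5 of 19 neuron and ganglion markers, 6 of 13 glial and melanocyte precursor markers, 3 of 14 endothelial, 2 of 14 blood cell, 4 of 16 epithelial and endoderm, and 3 of 12 mesoderm and skeletal muscle markers (adjusted p 0.29, 1, 0.23, 0.10, 0.26 and 0.37). Elavl4 (4.74 and 5.62), an RNA-binding protein of neurons, and Erbb3 (4.08 and 6.16), a receptor of glial precursors, were among the markers with CHD7, as were Erg, Klf1, Epcam and Tcf15. Within 500 bp, endothelial and blood cell markers were called lower (log2 odds ratio −2.64 each), as were blood cell markers within 2.5 kb (−2.24). With regions found in either library, BMP and TGF-beta (1.92), WNT (1.41), NOTCH (2.59) and smooth muscle and matrix genes (2.03) were called higher.

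H3K27ac at boundaries passed the test in 8 lists. Chromatin regulators (25 of 28) and housekeeping genes (25 of 27) had it more often than the 47.6% of other genes (Fisher's exact test, adjusted p 5.18e-05 and 3.27e-05). It was less frequent at pharyngeal arch patterning genes (5 of 25, adjusted p 0.0206), posterior Hox genes (0 of 16, 0.000272), cardiomyocyte markers (0 of 14, 0.000515), endothelial markers (0 of 14, 0.000515), epithelial and endoderm markers (2 of 16, 0.0144) and adult tissue genes (4 of 30, 0.000515). Here too the clustered posterior Hox genes are not independent members. The remaining lists had 10 of 24 neural crest specifiers, 19 of 32 cardiac neural crest, 5 of 15 anterior Hox, 21 of 34 semaphorin and axon guidance, 20 of 30 BMP and TGF-beta, 21 of 31 WNT, 12 of 20 NOTCH, 12 of 23 retinoic acid and hedgehog and 14 of 20 smooth muscle and matrix genes. Markers of neurons and ganglia (6 of 19), glia and melanocyte precursors (5 of 13), blood cells (3 of 14) and mesoderm and skeletal muscle (3 of 12) did not pass either. The 3 endothelial markers with CHD7, Erg (folds 3.89 and 4.11), Kdr (3.32 and 3.08) and Cldn5 (3.05 and 2.95), lacked H3K27ac, as did Snai2 and Ets1 among neural crest specifiers. The epithelial call (log2 odds ratio −2.40) was lost with a −log10 q of at least 10 (−2.03, adjusted p 0.0859) and with the 10000 peaks of lowest q (−2.24, 0.0528). BMP and TGF-beta signalling was called higher without H3K27ac replicate 2 (log2 odds ratio 1.33) and WNT signalling without H3K27ac replicate 1 (1.48), and both with regions found in either library (1.46 and 1.28). With a −log10 q of at least 10, neural crest specifiers (−2.63), anterior Hox genes (−3.61) and markers of neurons (−2.28), mesoderm (−3.30) and blood cells (−3.52) were called lower, and within 2.5 kb semaphorin and axon guidance genes (1.36) were called higher.

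**Figure D3:**
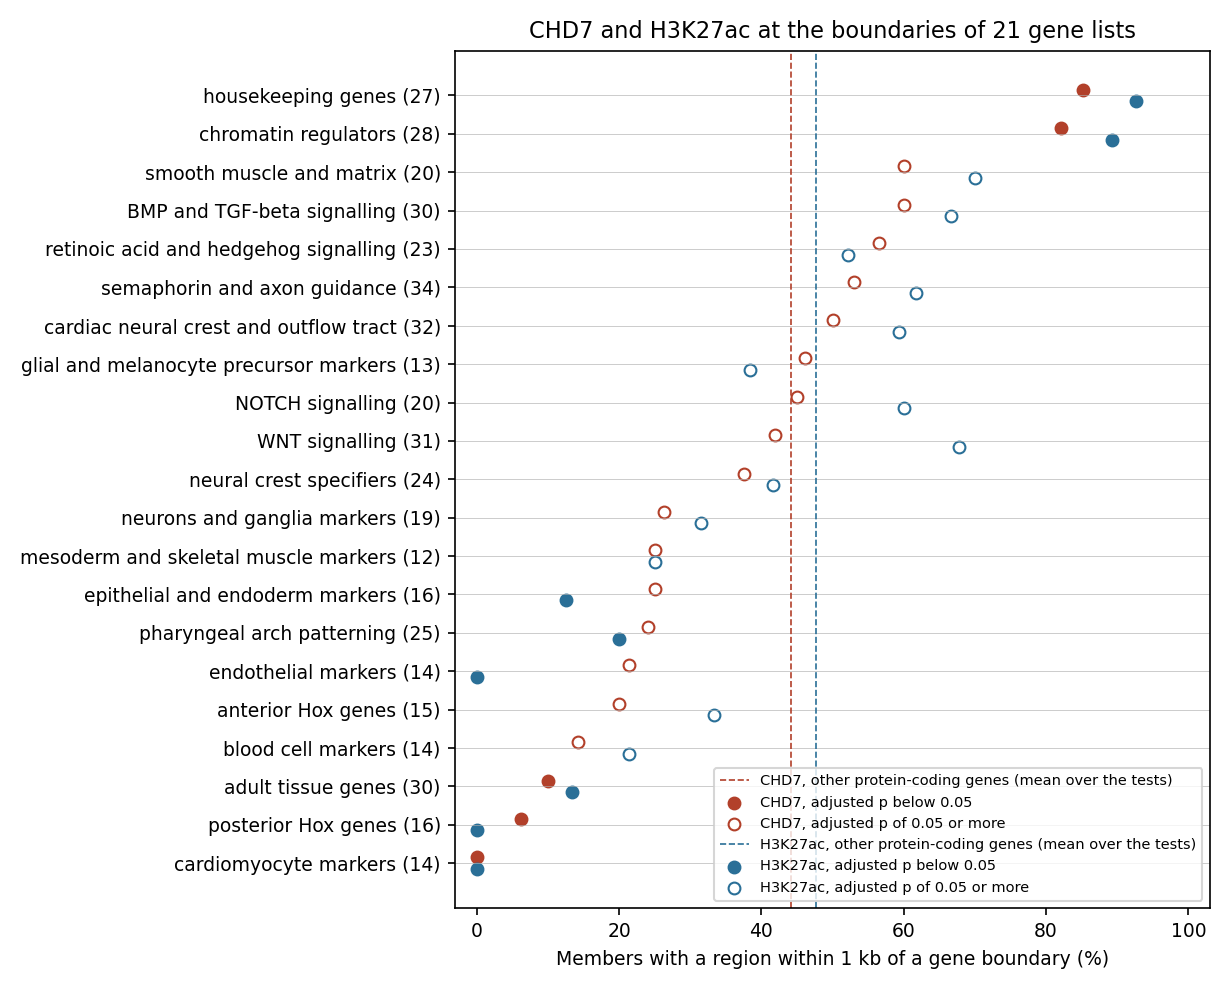
Share of the members of each gene list (number of members in parentheses) with a CHD7 or an H3K27ac consensus region within 1 kb of a gene boundary, in percent, with filled points for lists that passed Fisher's exact test after adjustment and dashed lines for other protein-coding genes. Housekeeping genes and chromatin regulators lie above both lines, between 82.1% and 92.6%, and cardiomyocyte markers lie at 0 for both antibodies.

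Away from boundaries, distal CHD7 regions exceeded matched random lists in 7 of the 21 lists. Neural crest specifiers had 34 such regions, 1.42 per member against 0.74 ± 0.25 (SD over random lists), anterior Hox genes 10 (0.67 against 0.14 ± 0.11), semaphorin and axon guidance genes 63 (1.85 against 0.82 ± 0.22) and WNT genes 44 (1.42 against 0.58 ± 0.19). Retinoic acid and hedgehog genes had 32 (1.39 against 0.57 ± 0.22), chromatin regulators 41 (1.46 against 0.49 ± 0.18) and mesoderm and skeletal muscle markers 14 (1.17 against 0.42 ± 0.25). Their adjusted permutation p-values (one-sided) were 0.0366, 0.0176, 0.0021, 0.0049, 0.0176, 0.0021 and 0.0366. Few members carried some of these counts. Chd2 had 14 of the 41 regions of chromatin regulators, 5 of 15 anterior Hox genes had any, and Ebf2 (6), Uncx (4) and Meox1 (3), picked after their values were seen, had 13 of the 14 regions of mesoderm and skeletal muscle markers. Ets1 had 5 distal CHD7 regions, Sema3a, a secreted axon guidance cue, had 6, and Robo1, Ror2 and Rxra had 3 each. The remaining lists had 25 distal CHD7 regions at cardiac neural crest genes, 20 at pharyngeal arch, 0 at posterior Hox, 33 at BMP and TGF-beta, 15 at NOTCH, 13 at smooth muscle and matrix, and 12 at housekeeping genes. Markers of neurons and ganglia had 17, glia and melanocyte precursors 9, cardiomyocytes 2, endothelium 6, blood cells 7 and epithelium and endoderm 11, and adult tissue genes 6. With a −log10 q of at least 10, or with the 10000 peaks of lowest q, 0 lists passed. Without CHD7 replicate 1, 9 lists passed, and without CHD7 replicate 2, 10 lists passed, with BMP and TGF-beta and NOTCH signalling called in both cases and housekeeping genes in the second.

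Distal H3K27ac regions exceeded matched lists in 4 lists. BMP and TGF-beta genes had 31 regions (1.03 per member against 0.45 ± 0.17, SD over random lists), WNT genes 34 (1.10 against 0.40 ± 0.16), chromatin regulators 31 (1.11 against 0.36 ± 0.16) and housekeeping genes 12 (0.44 against 0.16 ± 0.09), with adjusted permutation p-values of 0.0357, 0.0241, 0.0189 and 0.0467. Chd2 had 8 of the 31 regions of chromatin regulators, and the 12 regions of housekeeping genes lay at 5 of 27 members. Neural crest specifiers had 18 distal H3K27ac regions, cardiac neural crest genes 24, pharyngeal arch genes 7, anterior Hox genes 5, posterior Hox genes 0, semaphorin and axon guidance genes 33, NOTCH genes 15, retinoic acid and hedgehog genes 18, and smooth muscle and matrix genes 11. Markers of neurons and ganglia had 5, glia and melanocyte precursors 4, cardiomyocytes 1, endothelium 6, blood cells 4, epithelium and endoderm 6, and mesoderm and skeletal muscle 5, and adult tissue genes 1. Lists called for distal CHD7 alone also lay above matched lists for H3K27ac. Semaphorin genes had 0.97 per member against 0.49, retinoic acid and hedgehog genes 0.78 against 0.38 and anterior Hox genes 0.33 against 0.12. Neural crest specifiers had 0.75 against 0.47 and mesoderm markers 0.42 against 0.31 (adjusted permutation p 0.0535, 0.0969, 0.148, 0.218 and 0.563 in that order). The calls thus set no difference between the antibodies. Without H3K27ac replicate 1, 7 lists passed, and without H3K27ac replicate 2, 8 lists passed, and housekeeping genes were called in neither case. With a −log10 q of at least 10, 1 list passed, and with the 10000 peaks of lowest q, 2 passed, and the calls of BMP and TGF-beta and WNT genes were lost in both cases.

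**Figure D4:**
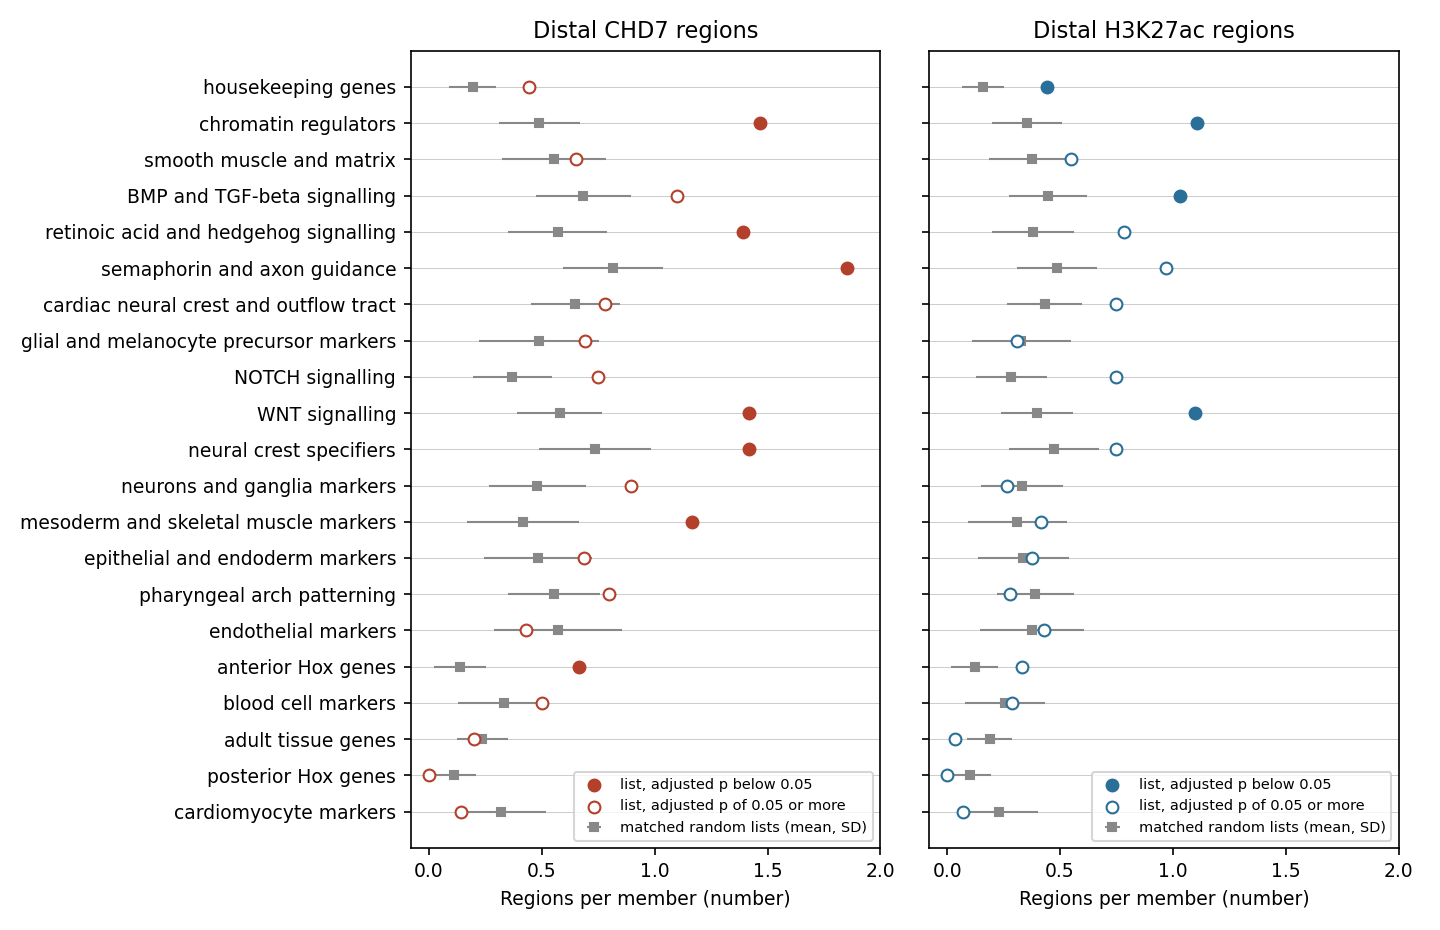
Distal consensus regions per member of each gene list (points, filled where the adjusted permutation p is below 0.05) and in 10000 matched random lists (grey squares, mean and SD), for CHD7 on the left and H3K27ac on the right. Semaphorin and axon guidance genes have the highest value for CHD7, 1.85 regions per member, and chromatin regulators the highest for H3K27ac, 1.11.

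Single genes with many distal CHD7 regions included Zfp608 and Chd2. Zfp608, a zinc finger gene on chromosome 18, had 15, of which 3 overlapped H3K27ac, and Chd2, a relative of Chd7, had 14, of which 7 did. Skap2, beside the Hoxa cluster, had 9, with 2 overlapping H3K27ac, and 1700001O22Rik, BC107364 and Cstad had 9 each, with 5, 6 and 7. Gm52481 on the Y chromosome had 21, Gm40363 12, Mid1 11 and Hrh1 9, but input peaks covered 8, 6, 4 and 4 of these. Of the 10 longest stretches of H3K27ac, 3 lay over histone gene clusters of chromosome 13. The longest covered 13.95 kb in 21 regions from 23530229 to 23586896, around H4c8, H2ac10 and H3c8, and 20 of its regions overlapped CHD7. The next in covered length lay nearest to Atg7 (13.7 kb), Alkbh8 (8.69 kb), Gm13286 (7.40 kb) and Atp5d (6.86 kb), followed by the histone clusters around H1f2 (23737923 to 23764204, 6.82 kb) and H2ac12 (22028898 to 22051534, 6.35 kb), which held 11 and 7 regions, all with CHD7. The stretch at the start of chromosome 9 nearest to Alkbh8 had an input peak in all 14 of its regions, and that at Atg7 in 9 of 24. Stretches nearest to Gm13286, Atp5d, Chd2 and Mrpl58 overlapped no input peak, and that nearest to Gm40363 overlapped 1.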

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

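The sequences of the assembly that are not placed on a chromosome entered none of the comparisons, and the count reported here was chosen after the lists had been seen. On 5 such sequences, both CHD7 libraries had more peaks than either input library. On a sequence assigned to chromosome 4 they had 5 and 11 peaks, against 1 in the inputs, and on another 2 and 2, against 0. Unassigned sequences had 8 and 9 peaks against 3, 2 and 3 against 0, and 1 and 1 against 0. The H3K27ac libraries had 1 and 2 peaks on the first of these sequences and 1 and 1 on the last. They had 2 and 2 on that with 8 and 9 CHD7 peaks, and 0 on the others. On each of the other 8 such sequences with CHD7 peaks, and on the mitochondrial genome, at least 1 input library had as many peaks as either CHD7 library, such as 61 and 63 against 23 and 21 on an unassigned sequence. No explanation was tested, and the lists differ greatly in length, so these small counts set no level between the antibodies and the input.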

How the results depend on the processing

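Recomputed values that answer a comparison kept their direction and their side of the threshold, or a count within 1.5 times, in 100 cases, moved in 11 and reversed in 1. For single gene lists, 550 values kept their direction and their side of the threshold, 50 newly passed it, 28 no longer passed it and 2 reversed. A reversed value had passed and then lay in the other direction, whether or not it passed there. The one-sided test of distal regions cannot call a list lower. The log2 fold difference between CHD7 peaks with and without H3K27ac was −0.00518 when peaks of both antibodies had a −log10 q of at least 10. It was 0.0508 with the 10000 peaks of lowest q of each library. With a −log10 q of at least 10, neural crest specifiers (0 distal CHD7 regions per member) and retinoic acid and hedgehog genes (0.0435) lay below matched lists. Under that limit, 2 lists were called for CHD7 at boundaries, 0 for distal CHD7 and 1 for distal H3K27ac; with the 10000 peaks of lowest q, 2, 0 and 2; with regions found in either library, 9, 11 and 9. Leaving out each H3K27ac library gave 7 and 8 lists for distal H3K27ac. The cause was not tested in any of these cases. Among results that kept their call, the same limit moved the share of H3K27ac regions overlapping CHD7 to 27.8%, and the odds ratio of H3K27ac with CHD7 over genes lay between 14.8 and 81.9 over all alternatives. The share of CHD7 regions overlapping H3K27ac lay between 46.7% (without CHD7 replicate 2) and 66.1% (without H3K27ac replicate 2). Leaving libraries out of a group removes its consensus, so the overlap between replicates had no such alternative, and the motif counts were not run. The depth of the libraries is unknown, so weak peaks found in 1 library alone could not be set against its depth.

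The replicate block compared same-numbered libraries. It used the peaks of single libraries in place of consensus regions. On average, 54.1% of CHD7 peaks overlapped H3K27ac and 65.2% of H3K27ac peaks overlapped CHD7, and no call changed. These shares are thus not comparable with those of consensus regions. The Pearson correlation of the deviations of same-numbered libraries was 0.00032 across 11766 regions, so the numbers were not treated as pairs.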

Other observations

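All tests in this part were chosen after the main results had been seen; for the shares matched on H3K27ac or CHD7 fold, the q-values on the X chromosome, the input peaks at tRNA genes and the H3K27ac peaks of either library, the bounds were set before those values were known, except over 10 lists. Clustered histone genes, which supply histones during DNA replication, nearly all carried CHD7. CHD7 lay at a boundary of 67 of 68 such genes and H3K27ac at 62 of 68, with odds ratios against other protein-coding genes of 85.3 and 11.4 (Fisher's exact test adjusted over 5 gene families, p 9.41e-23 and 2.72e-14). Ribosomal protein genes had CHD7 at 68 of 83 and H3K27ac at 76 of 83 members, and zinc finger genes named Zfp at 232 and 295 of 397. Olfactory receptor genes had CHD7 at 2 and H3K27ac at 0 of 1109 members, and vomeronasal receptor genes at 2 and 3 of 352. Neighbours within a cluster can share a region, so the members are not independent.

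Among non-coding genes, tRNA genes had CHD7 within 1 kb in 252 of 403 cases (62.5%) and H3K27ac in 166 (41.2%), while microRNA genes had 126 and 130 of 1228 and small nuclear RNA genes 72 and 68 of 997. Long non-coding RNA genes had CHD7 in 2052 and H3K27ac in 2040 of 12637 cases, and small nucleolar RNA genes in 75 and 102 of 1330.

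CHD7 was found at tRNA genes more often than H3K27ac, in a ratio of 1.52, but distal CHD7 regions also outnumbered distal H3K27ac regions by 1.49 (9750 against 6542), so the ratio by itself sets no preference. Rotated CHD7 regions lay within 1 kb of 2.13% of tRNA genes (permutation p = 0.001, the smallest possible). Among 138 tRNA loci more than 2 kb from any protein-coding boundary, with genes up to 10 kb apart joined, 75 had CHD7 and 56 H3K27ac, and 19 had CHD7 alone and 0 H3K27ac alone (exact p against even odds 3.81e-06), which argues against neighbouring protein-coding genes as the whole source. The distal CHD7 regions were then cut to the number of distal H3K27ac regions. After a cut by fold, 14 loci had CHD7 alone and 1 H3K27ac alone (exact p = 9.77e-04). The excess passed the test in 0.30% of 1000 random cuts, with a median of 14 loci for CHD7 alone and 14 for H3K27ac alone. A random cut also takes CHD7 from loci that held both, so its outcome is no evidence for the longer list. The longer list and a preference of CHD7 were thus not told apart. An input peak lay near 1.19% of the tRNA genes with CHD7, but input peaks overlapped 1.46% of all CHD7 regions, so background stays open too, and neither reads shared between near-identical tRNA copies nor a biological explanation was tested.

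On the X chromosome both were found at fewer genes, CHD7 at 11.9% and H3K27ac at 24.4% of 963, against 46.2% and 49.3% of autosomal genes. CHD7 lay at 105 of the 235 X-linked genes with H3K27ac at a boundary (44.7%) and at 8462 of 10136 such autosomal genes (83.5%; Fisher's exact test, p 2.04e-40), and the shares on single autosomes ran from 77.7% to 90.3%. Autosomal genes matched on H3K27ac fold had CHD7 in 80.2% of cases, so that the X-linked share lay at −35.6 percentage points from them and below the lowest of 1000 draws (72.8%), which argues against weaker H3K27ac as the whole cause, although 18 of 20 X-linked genes had CHD7 in the highest decile of H3K27ac fold (95.3% of autosomal ones) and 13 of 29 in the next (93.0%). Fewer reads on the X chromosome may lower the power to call peaks there. X-linked peaks had a −log10 q of 0.941 times that of autosomal peaks of the same fold (mean of 4 ChIP libraries, each below 1). The ratio was 0.947 and 0.953 in the CHD7 libraries and 0.911 and 0.951 in the H3K27ac libraries. Only called peaks enter this ratio, so peaks lost on the X chromosome are not counted. The median −log10 q of all peaks was 4.99 and 5.31 for CHD7 and 7.14 and 7.40 for H3K27ac. A similar deficit can thus remove more CHD7 than H3K27ac peaks, and the ratios do not weigh against lost power. Whether a deficit of this size can account for the difference was not tested. The labels give no sex for the embryos, and no biological explanation was tested.

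Distal CHD7 near developmental regulators may lie more often at sites without H3K27ac, but the lists were grouped after the list values of both antibodies had been seen, so the odds ratios do not test this independently. Over single lists, pharyngeal arch (2 of 20 distal CHD7 regions with H3K27ac) and anterior Hox genes (0 of 10) passed as lower (Fisher's exact test adjusted over 20 lists, p 0.0336 for both) and housekeeping genes (10 of 12) as higher (0.0483), while neural crest specifiers (8 of 34), neuron and ganglion markers (3 of 17) and mesoderm and skeletal muscle markers (2 of 14) did not pass (0.109, 0.117 and 0.109). Apart from housekeeping genes, the 5 lists named here together had H3K27ac at 15 of 95 regions, an odds ratio of 0.237, and the 10 lists of neural crest, cardiac, arch, Hox, semaphorin and signalling genes, which leave out both marker lists and include WNT (21 of 44), BMP and TGF-beta (13 of 33), semaphorin (22 of 63) and cardiac neural crest genes (8 of 25), had it at 82 of 265 (30.9%) against 44.3% of 7430 others, an odds ratio of 0.563 (95% interval 0.432 to 0.733). Lists outside these groups also lay below other regions, namely adult tissue genes (1 of 6) and glial and melanocyte precursor markers (2 of 9). So did blood cell (2 of 7) and endothelial markers (2 of 6) and smooth muscle and matrix genes (5 of 13). Chromatin regulators (25 of 41), epithelial and endoderm markers (6 of 11) and cardiomyocyte markers (1 of 2) lay above. None of these lists passed the adjusted test. The difference from regions matched on CHD7 fold and distance was −22.3 percentage points for the 5 lists, which their choice can enlarge, and −8.35 for the 10 lists, whose share lay below the 5th percentile of 1000 draws (34.7%) and just above the lowest (30.6%), but these too were grouped after their values were seen, so a link to these genes and their weaker CHD7 or distance cannot be told apart. Counting H3K27ac peaks of either library left the odds ratios at 0.380 and 0.587. The share rose from 15.8% to 33.7% for the 5 lists, and from 44.2% to 57.2% for other regions. For the 10 lists it rose from 30.9% to 44.2%, and from 44.3% to 57.4% for others. Because the lists were grouped after their values were seen, this does not decide whether peaks missed in a single library are the cause. Marks of poised or repressed chromatin were not analysed here.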
